A study of Mus musculus with 2 samples.

How the data were processed

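Histone H3 trimethylated at lysine 36 (H3K36me3), a mark laid down over the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse forebrain at embryonic day 14.5. Per the labels, there were 2 biological replicates of 1 group: replicate 1 was a pool of 24 embryos and replicate 2 a pool of 34, of both sexes, of the strain labelled B6NTac;B6NCrl, with a library fragment range of 300 to 500 bp. There was no second tissue, stage or antibody among the samples analysed here, so the comparisons were between the replicates and between parts of the genome.

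The authors deposited 4 peak lists on the mm10 assembly. Per the submitters' text files, each replicate's own list derived from that replicate's alignment together with further files that are not described there, 1 list derived from both alignments together, and the replicated list derived from that joint list and from each replicate's own list. The aligner, the peak caller, their versions and the rule for a replicated peak are not given in the sources used here. The lists are in narrowPeak format, and each peak carries values that the authors deposited with it: a score from 10 to 1000, a fold enrichment, which is a linear ratio over a background that is not stated, a −log10 p-value, a −log10 q-value and a summit position. These are the authors' own values for each peak, and they were used only to describe, rank or filter peaks within a list. The lowest −log10 p in the lists was 2.01, 2.05, 2.03 and 2.03 for replicate 1, replicate 2, the joint list and the replicated list. Sequencing depth is unknown, because the peak lists hold no read counts, so no interval or floor that needs depth is given. A locus without a peak may carry the mark below the authors' threshold.

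Gene bodies, exons and introns were taken from GENCODE M21 on GRCm38, the same assembly as mm10. On the 21 assembled chromosomes, 0 peaks lay beyond a chromosome end. A gene body ran from the first to the last annotated base. The annotation held 21938 protein-coding genes on chromosomes 1 to 19, X and Y, of which 17184 overlapped no other protein-coding gene, and 13374 long noncoding RNA (lncRNA) genes. Overlapping peaks were merged, and the share of each gene body covered by peaks was computed from the replicated list and from each replicate's own list. The mean and SD of the replicates' own lists (n = 2) describe how the replicates differ. This SD is not the error of the value from the replicated list, which can lie well outside it. The replicated list can cover more of a gene than either own list, since its peaks were called on both replicates together.

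The following choices were made before the data were examined. A gene counted as marked when peaks covered at least 10% of its body. Overlap between replicates was the share of bases covered by both own lists among those covered by either (the Jaccard index), set against 1000 random rotations of replicate 2's peaks along each chromosome. The share of peak bases within protein-coding gene bodies was set against 1000 rotations in the same way. Position along the gene was measured in 10 equal parts from 5′ to 3′ over protein-coding genes of at least 10 kb that overlapped no other. The exon to intron ratio compared the shares of exonic and intronic bases covered, and the X to autosome ratio the shares of gene-body bases covered. The 95% intervals of position and of the exon to intron ratio come from 1000 bootstrap draws over genes. They describe variation between genes in these libraries, since genes are not independent replicates.

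There were 31 fixed gene lists, 25 of chosen symbols and 6 by symbol pattern, covering forebrain progenitors and neurons, ubiquitous functions, other cell types that a dissected forebrain could hold, other tissues and large gene families. Every chosen symbol was found in the annotation. Each list's median share covered was placed as a percentile among 10000 random lists of protein-coding genes with the same number of members, matched on gene length in 20 bins. A list was said to stand apart when it lay outside the middle 95% of random lists. Because many random lists have a median of 0, the lower bound cannot be reached by the median, and the percentile of the mean, an alternative also fixed beforehand, is given for lists with little cover. No p-value across genes was computed, since the libraries form 1 group.

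The genes and peaks named in the text follow a rule fixed at the same time: the 3 members of each list with the largest share covered and the 1 with the smallest, the 10 protein-coding genes of at least 5 kb with the largest share covered, the 10 with the most bases covered, the 5 peaks of largest fold and the 5 widest, the 5 genes of at least 5 kb with the largest difference between replicates in each direction, and the 5 widest peaks outside annotated genes. Ties were broken by symbol, and some members are left out for length. Names added to these were chosen after their values were seen, and the text says so.

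Alternatives were the joint list, only replicated peaks with a fold at or above the list's median or a q of at most 0.01, each replicate's own list alone, other shares of the body for a marked gene (any base, 5% and 25%), merging of peaks within 1 kb, unmatched random lists, the mean for the median, other gene lengths (50 kb and 2 kb), internal exons without the outer 1 kb of the gene, all annotated genes, autosomes alone, the same number of strongest peaks from each own list, identical coordinates for a replicated peak, and stricter overlap between peaks (50%). Leaving out genes that overlap another protein-coding gene, and percentiles of the mean with each random gene drawn from the 50 nearest in length to the member, were added after seeing the data. The last was added because the longest length bin also holds genes far shorter than the long neuronal genes.

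Scripts were written in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9. They were tested on simulated data. Coverage differed from a base-by-base count in 0 of 10000 intervals. Among genes covered for 20% of their body by simulated peaks 200 of 200 were counted as marked, and among genes covered for 5% 0 of 200 were. Of 400 random lists of 15 genes, 4.0% fell outside the middle 95% by the mean, and 1.75% lay above it by the median. Of 200 lists of 15 genes raised by 30 percentage points, 100% lay above it by the mean.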

Results

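H3K36me3 was profiled in the forebrain of mouse embryos at embryonic day 14.5, when the cerebral cortex and ganglionic eminences hold dividing progenitors beside young neurons. The group comprised 2 biological replicates, pools of 24 and 34 embryos. Replicate 1's own list held 166686 peaks over 95.2 Mb and replicate 2's held 137656 peaks over 75.9 Mb. The replicated list held 110106 peaks over 102.6 Mb, which is 3.88% of the assembled genome. Its peaks had a median width of 565 bp and a median fold enrichment, as the authors give it, of 3.96. Sequencing depth is unknown for both replicates. All coordinates are on mm10, and all shares of gene bodies are from the replicated list unless a replicate is named, followed by the mean ± SD of the replicates' own lists.

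The replicates were compared first. Both lists marked the same broad set of genes: 6721 protein-coding genes had at least 10% of the body covered in both, 978 reached this in replicate 1 alone and 56 in replicate 2 alone. The own lists shared 53.1% of the bases covered by either (59.4 Mb of 111.7 Mb). None of 1000 rotations of replicate 2's peaks gave as much overlap, with a rotated median of 1.87% and a maximum of 2.84%. Of replicate 1's peaks 63.6% overlapped a peak of replicate 2 by at least 1 bp, and of replicate 2's peaks 82.9% overlapped a peak of replicate 1. Shared peaks were the stronger ones. In replicate 1, 37.0% of the weakest 25% of peaks by p overlapped replicate 2, against 94.5% of the strongest 25%, and in replicate 2 these shares were 67.9% and 97.9%.

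Across the 21938 protein-coding genes the share of the body covered correlated between replicates with Pearson's r of 0.977 and Spearman's rho of 0.957, where genes are not independent replicates. Genes without cover in either list count in both values, so these do not measure agreement among covered genes alone. Coverage was higher in replicate 1 for 88.4% of the 11204 genes with any cover, and the median SD between replicates over these genes was 2.93 percentage points. The genes with the largest excess in replicate 1 were Cuta (55.3% against 20.1%), Bcl2l12 (44.9% against 10%), B3gnt8 (44.7% against 9.81%), Tfpt (52.4% against 18.0%) and Asphd2 (57.3% against 24.6%). Those with the largest excess in replicate 2 were Gpc2, which encodes a glypican (31.5% in replicate 1 against 53.0% in replicate 2), Cnpy4 (19.4% against 35.3%), Mif4gd (23.5% against 38.8%), Fbxo44 (39.9% against 55.0%) and Avpi1 (14.1% against 28.2%). These 10 genes span 5052 to 10513 bp, and 6 of them overlap another protein-coding gene. With 2 replicates of 1 group, no test of a single gene's difference was possible.

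**Figure D1:**
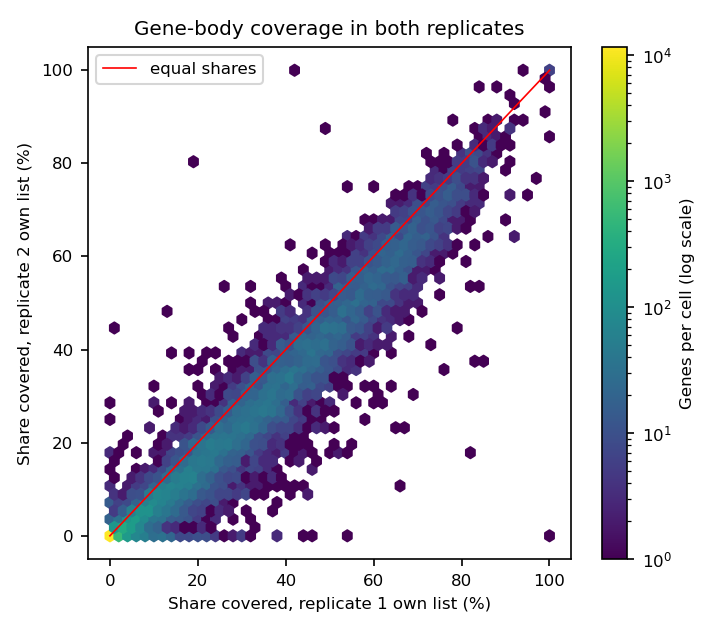
Share of each protein-coding gene body covered by H3K36me3 peaks in replicate 1's own list (x axis, percent) and replicate 2's own list (y axis, percent), with cells coloured by the number of genes on a log scale and a red line where the shares are equal. Most of the 21938 genes lie along the line, and 88.4% of the 11204 genes with any cover lie on the replicate 1 side.

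The replicated list held 76.4% of the joint list's peaks (110106 of 144060), all at the same coordinates. The 33954 peaks left out had a median fold of 2.84 and a median width of 245 bp. Of the replicated peaks, 71.9% overlapped a peak in both own lists, 17.4% in replicate 1's list only, 7.88% in replicate 2's list only and 2.83% in neither. Those in both own lists held 88.9% of the covered bases.

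The next question was where the mark lies in the genome. Protein-coding gene bodies held 95.1% of the covered bases (own lists 95.1% ± 0.313, SD, n = 2) and make up 39.3% of the assembled genome. Rotated peaks had a median of 42.0% and a maximum of 46.0% in gene bodies, and 0 of 1000 rotations reached the observed share. With at least 10% of the body covered, 7646 of 21938 protein-coding genes (34.9%) were marked, and the own lists gave 7238 ± 652 (SD, n = 2). The marked share varied with gene length. It was 17.8% of genes under 5 kb, 38.5% from 5 to 20 kb, 45.8% from 20 to 100 kb, 20.1% from 100 to 500 kb and 1.3% above 500 kb (3 of 230). Any replicated cover was found in 19.6%, 44.5%, 60.1%, 56.3% and 39.6% of the genes in these classes. A long gene needs more covered bases to reach 10% of its body, so the low marked share of long genes does not mean that they lack peaks.

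Genes with the largest share covered are given next. Kpnb1, the nuclear import receptor importin beta 1 (ENSMUSG00000001440.5, chromosome 11, 97159714 to 97187881), was covered for 94.1% (own lists 89.3% ± 2.77, SD, n = 2). The splicing factor genes Sf3a1 and Sf3b3, the latter overlapping Cog4, were covered for 93.5% (88.7% ± 0.832) and 91.1% (84.9% ± 1.71). Kmt2b, a histone H3 lysine 4 methyltransferase, reached 91.0% (87.7% ± 3.61), Rnf40, a ubiquitin ligase for histone H2B, 93.3% (86.8% ± 2.49), and Trrap, a scaffold of histone acetyltransferase complexes, 92.5% (86.8% ± 1.88). Scrib, a cell polarity gene, reached 91.3% (87.7% ± 0.138) and Gigyf1, which overlaps Epo, 96.0% (92.5% ± 2.64). Prss53 had the largest share, 98.8% (92.1% ± 5.89), and overlaps Zfp646, so its cover cannot be assigned to it alone, which holds for Gigyf1 and Sf3b3 too. By bases covered, the leading genes that overlap no other protein-coding gene were Syne2, a nuclear envelope protein gene (166710 bp, 56.9% of the body), the cytoskeletal linker gene Macf1 (124003 bp, 37.0%) and Wdfy3 (121586 bp, 51.3%). The annotated bodies of Gm20388 and Fgfr2 held more bases than Syne2, but each spans many other genes.

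**Figure D2:**
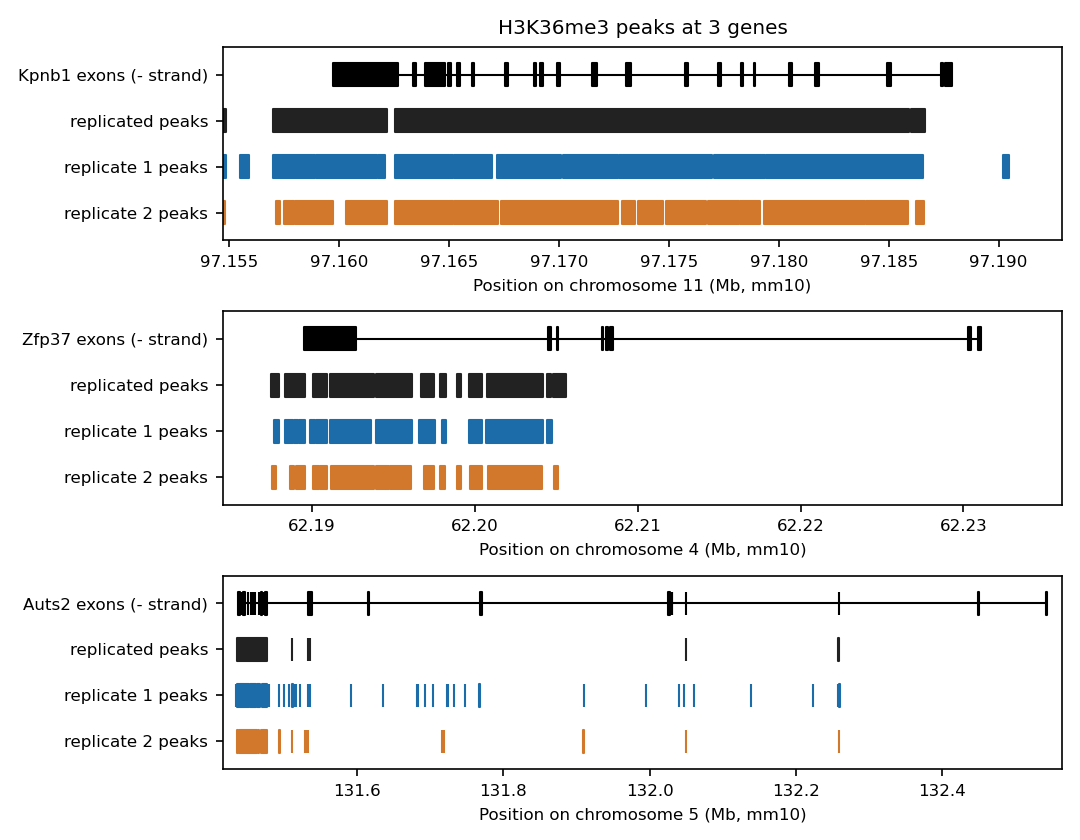
Exons of Kpnb1, Zfp37 and Auts2 (black, with a line for the gene body) above the replicated peaks and each replicate's own peaks, with position in Mb on mm10 along the x axis. Replicated peaks cover 94.1% of Kpnb1, and in Zfp37 they run over the 3′ part of the body and past its 3′ end. In Auts2, of which 3.59% is covered, they lie mostly at the 3′ end.

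The widest replicated peak, 28437 bp, lay in Dync1h1, the heavy chain of cytoplasmic dynein (chromosome 12, 110615486 to 110643922), with 27.6% of its bases in exons. The next widest lay in the chromatin remodelling gene Smarca4 (24008 bp), Kpnb1 (23407 bp), Scrib (23167 bp, reaching into K230010J24Rik) and Kmt2a (22442 bp). The 5 peaks with the largest fold enrichment all lay in zinc finger genes. They had folds of 14.2 in Zfp37 (chromosome 4, 62191121 to 62193841), 13.7 in Zfp146 (chromosome 7, 30160640 to 30164377), 13.3 in Zfp810 (chromosome 9, 22278114 to 22281176), 13.0 in Zfp157 (chromosome 5, 138454356 to 138459824) and 12.9 across Zfp865, Ccdc106 and Gm44973 (chromosome 7, 5028460 to 5034045). The last exon made up 57.7%, 52.4%, 38.1% and 72.2% of the peaks in Zfp37, Zfp146, Zfp810 and Zfp157. In the peak across Zfp865, Ccdc106 and Gm44973 last exons made up 23.0%. Among the 100 peaks of largest fold 25 lay in numbered Zfp genes, against 1.84% of all replicated peaks.

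Among the fixed gene lists, those of widely used cellular functions had the highest cover. By the median, 7 of the 31 lists lay above the middle 95% of length-matched random lists, and the same 7 did so in each replicate's own list. All 18 splicing and RNA processing genes were marked, with a median of 73.3% (percentile 100), led by Snrnp200 at 87.7% (83.3% ± 4.16, SD, n = 2), Prpf8 at 87.7% (83.8% ± 0.915) and Sf3b2 at 85.3% (78.9% ± 1.54). All 16 cell cycle genes were marked, with a median of 62.4% (percentile 100). Top2a, the DNA topoisomerase of dividing cells, reached 77.3% (61.7% ± 1.61), and the replication licensing genes Mcm3 and Mcm4 76.8% (57.8% ± 3.02) and 76.6% (61.1% ± 12.5). Of the 15 ubiquitous genes 14 were marked (median 56.9%, percentile 99.99), with Eef2 at 79.6% (76.1% ± 5.56) and Actb at 73.2% (64.3% ± 8.16). The X-linked Hprt was the lowest at 4.39% (4.41% ± 2.68). The other X-linked member, Pgk1, named after its value was seen, stood at 31.8% (21.6% ± 9.98). Of the 20 ribosomal protein genes 17 were marked (median 54.8%, percentile 100), from Rps3 at 82.5% (81.4% ± 0.448) to the X-linked Rpl10 at 0, which had cover in replicate 2 alone (8.18%). Of the 20 chromatin regulators 18 were marked (median 51.0%, percentile 100), led by Kmt2d at 85.5% (83.6% ± 1.59) and Smarca4 at 76.7% (72.5% ± 2.21). The de novo DNA methyltransferase Dnmt3b was the lowest of these at 2.29% (4.00% ± 3.13), and the maintenance enzyme Dnmt1 stood at 67.0% (64.3% ± 0.238). Of 366 numbered Zfp genes 231 were marked, with a median of 23.4% (percentile 100) and Zfp869 the highest at 95.4% (92.0% ± 2.96).

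**Figure D3:**
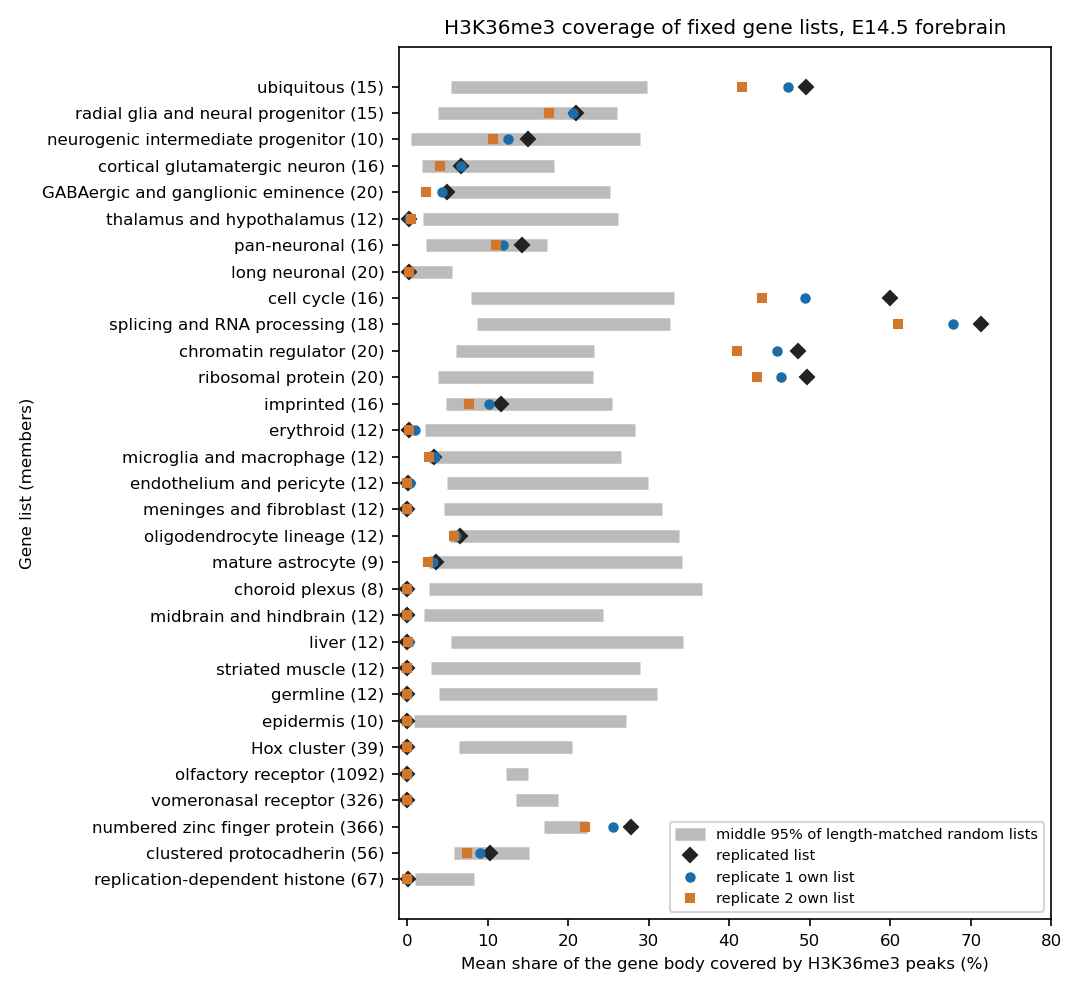
Mean share of the gene body covered by H3K36me3 peaks (x axis, percent) for each of the 31 fixed lists, with the number of members in brackets, from the replicated list (diamonds) and the own lists of replicate 1 (circles) and replicate 2 (squares). Grey bars hold the middle 95% of means of random lists matched on gene length, computed on the replicated list; splicing and RNA processing genes lie above them and the olfactory receptors at 0.

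Lists of forebrain progenitor and neuronal genes were measured in the same way. The pan-neuronal list, also among the 7, had 9 of 16 members marked and a median of 10.6% (percentile 99.69), with the neuronal RNA-binding gene Elavl3 at 49.3% (39.2% ± 1.90), the neuronal tubulin gene Tubb3, inside the annotated Gm20388, at 43.1% (35.0% ± 9.78) and Dpysl3 at 29.0% (25.9% ± 0.453). Syt1, a synaptic vesicle gene of 513333 bp, was covered for 0.0505%. This list fell to percentile 90.28 with unmatched random lists and 89.62 by the mean. Radial glia and neural progenitor genes lay just under the bound, with 10 of 15 marked, a median of 17.9% and percentile 97.15. They lay at 98.55 and 98.62 in the own lists of replicates 1 and 2, at 94.94 with unmatched random lists and at 89.02 by the mean. Vim, Notch1 and Nes led them at 48.8% (43.9% ± 4.70), 47.1% (43.5% ± 0.881) and 38.1% (31.1% ± 8.18), and Fabp7 had no peak. Of the intermediate progenitor genes 3 of 10 were marked, the Notch ligand gene Dll1 at 54.2% (49.5% ± 2.79), Btg2 at 46.4% (32.8% ± 2.40) and Mfng at 42.5% (28.0% ± 8.14), while Eomes had no replicated peak. The list's median of 0 lay at percentile 41.33, at 81.99 in replicate 1's own list, at 42.64 in replicate 2's and at 64.1 by the mean. Cortical glutamatergic genes had 3 of 16 marked, a median of 4.64% at percentile 96.45, and a mean of 6.69% at percentile 30.73 (79.75 by the median with unmatched random lists). With the joint list the median lay at percentile 98.2. In the own lists 3 were marked in replicate 1 (mean 6.73%) and 2 in replicate 2 (4.03%). In the replicated list the marked members were Neurod2 at 26.3% (21% ± 13.3), Cux1 at 19.2% (14.7% ± 3.17) and Fezf2 at 13.1% (6.65% ± 4.09). Fezf2 was under 10% in both own lists (3.76% in replicate 1 and 9.55% in replicate 2). GABAergic and ganglionic eminence genes had 4 of 20 marked, with Dlx2 at 27.3% (8.80% ± 0.528) and the GABA synthesis genes Gad2 and Gad1 at 21.5% (15.1% ± 4.97) and 19.2% (14.4% ± 4.61). Their mean of 4.97% lay at percentile 2.37. Replicate 1's own list marked 4 of the 20 with a mean of 4.33%, and replicate 2's marked 2 with a mean of 2.39%. Dlx2 was marked in neither own list (9.17% in replicate 1 and 8.43% in replicate 2). Of the 20 long neuronal genes none was marked, with Auts2 the highest at 3.59% (3.51% ± 0.421). Their mean of 0.236% lay at percentile 0.55 of lists matched in length bins, but at 30.12 when each random gene came from the 50 nearest in length, a match added after the data were seen. Thalamic and hypothalamic genes had 0 of 12 marked, with Lhx9 the highest at 1.43% (2.75% ± 2.55) and the mean at percentile 0.39.

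Markers of other cell types were mostly without peaks. By the mean, erythroid genes lay at percentile 0.57, endothelial and pericyte genes at 0.01, meningeal and fibroblast genes at 0.005 and choroid plexus genes at 0.16, with 0 members marked in each. Of the 12 microglial and macrophage genes 3 were marked (mean at percentile 3.68). Cx3cr1 (15.7%) and Csf1r (10.8%) overlap other protein-coding genes, and Fcer1g (13.9%, own lists 12.5% ± 1.74) does not. In the oligodendrocyte list 1 of 12 genes was marked (mean at percentile 4.13), Cnp at 72.2% (64.9% ± 2.02), which overlaps Dnajc7. In the mature astrocyte list 1 of 9 was marked (mean at percentile 3.53), Aldoc at 23.3% (16.2% ± 4.17). Fcer1g and Aldoc had only 667 and 1122 bp covered. Cover that runs past the 3′ end of a neighbouring gene was not separated from their own. No member was marked in the midbrain and hindbrain (percentile of the mean 0.03), liver (0.01), striated muscle (0.07), germline (0.025) or epidermis (0.43) lists. The same held for the 39 Hox genes, 1092 olfactory receptors, 326 vomeronasal receptors and 67 replication-dependent histone genes, of which only Hist3h2a, which overlaps Trim17, had any replicated cover (4.75%, own lists 0). Their means lay at percentile 0 for the Hox and both receptor lists and at 0.25 for the histone genes. Imprinted genes had 5 of 16 marked (percentile 57.23), led by Igf2r at 56.3% (46.4% ± 6.20), Meg3 at 47.2% (31.8% ± 7.04) and Peg3 at 35.1% (24.9% ± 6.01), and Cdkn1c had no peak. Clustered protocadherins had 21 of 56 marked (percentile 87.43, and 54.97 by the mean). All 21 are Pcdhg genes of 1 locus, whose annotated bodies overlap and share covered bases, so they are not separate marked genes. They were led by Pcdhgc5 at 41.6% (35.1% ± 1.62) and Pcdhgc4 at 41.6% (34.7% ± 3.21). The 22 members without cover were the Pcdhb genes, such as Pcdhb1.

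Coverage rose along genes from 5′ to 3′. Over 11002 protein-coding genes, each divided into 10 equal parts, the first 5 parts were covered for 10.9% and the last 5 for 22.3%, a difference of 11.4 percentage points (95% bootstrap interval over genes 11.1 to 11.8). The first part was covered for 2.04%, the ninth for 24.6% and the last for 24.4%. The replicates' own lists gave a difference of 9.76 ± 0.854 percentage points (SD, n = 2).

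**Figure D4:**
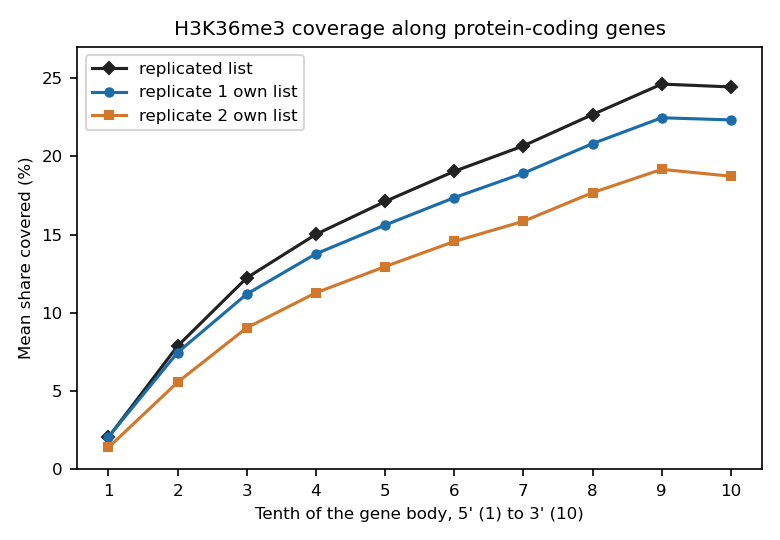
Mean share covered by H3K36me3 peaks (y axis, percent) in each of 10 equal parts of the gene body from 5′ to 3′ (x axis) over 11002 protein-coding genes, for the replicated list and the own list of each replicate. All 3 lines rise up to the ninth part, where the replicated list reaches 24.6%.

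Exons were covered more than introns. Peaks covered 27.4% of exonic and 7.76% of intronic bases of protein-coding genes, a ratio of 3.53 (95% bootstrap interval over genes 3.42 to 3.65), and the own lists gave 3.68 ± 0.245 (SD, n = 2). With internal exons alone and the outer 1 kb of each gene left out, the shares were 37.8% and 7.80%, a ratio of 4.85.

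Genes on the X chromosome were covered less than those on any autosome. Peaks covered 1.93% of X-linked and 9.75% of autosomal gene-body bases, a ratio of 0.198 (own lists 0.192 ± 0.0251, SD, n = 2). Single autosomes ranged from 7.02% on chromosome 14 to 14.2% on chromosome 11. On the X chromosome 108 of 948 protein-coding genes were marked (11.4%), against 7538 of 20807 on the autosomes (36.2%). X-linked replicated peaks had a median fold of 3.55 and a median width of 423 bp. With only peaks at or above the median fold the ratio was 0.138. On the Y chromosome 0 of 183 genes were marked.

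**Figure D5:**
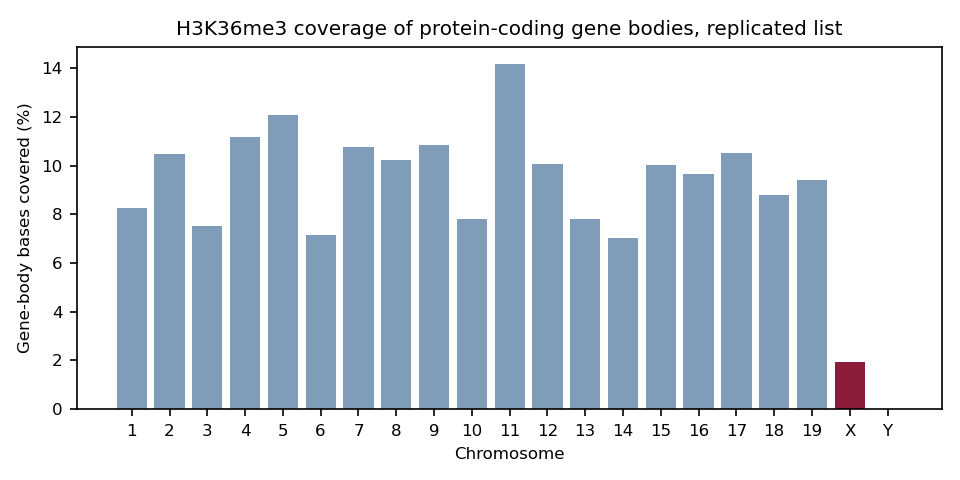
Share of protein-coding gene-body bases covered by replicated H3K36me3 peaks (y axis, percent) on each chromosome (x axis), with the sex chromosomes in red. Autosomes lie between 7.02% and 14.2%, the X chromosome at 1.93% and the Y chromosome at 0.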

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

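Both replicates' own lists held peaks on scaffolds outside the assembled chromosomes, which count in the totals and shares of peaks but in no measurement of genes or chromosomes. There were 10 such peaks in replicate 1 and 4 in replicate 2, each above the 3 set as the bound for a flag. The bound is not a test. With 1 group of 2 replicates, a sample far from the others or a difference between groups could not be sought. No test in this part was chosen after its result was seen. Technical explanations were weighed for 3 patterns of the report. No biological explanation was tested for any of them, since the design names no second group.

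The higher cover of exons over pooled windows was not fully accounted for by base composition or by repeats, each taken singly. Part of it remained within genes. In 50 bp windows of genes that overlap no other, internal exons were covered 5.27 times as much as introns, and 3.89 times (95% interval 3.74 to 4.05) at equal GC content of the surrounding 250 bp. In windows free of soft-masked repeats the ratio was 4.70 (4.49 to 4.92). With each gene's internal exons set against its own introns it was 2.01 (1.97 to 2.06), with each gene's introns weighted by its exon windows, while the pooled ratio weights them by intron windows. How much of the excess goes with differences between genes was not separated from this weighting. GC content and repeats were not held equal in the ratio within genes, so their part in it stays open. Position along the gene, with cover rising toward the 3′ end, was not held equal in any of these ratios. How much of the excess goes with position stays open.

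The low cover of the X chromosome was not accounted for by gene length or repeats. Marked X-linked genes were 0.350 of the number expected from autosomal genes of the same length (95% interval 0.292 to 0.411), and 0.314 of the autosomal share without that correction. In gene-body windows free of repeats the X to autosome ratio was 0.299 (0.218 to 0.383). These windows come from genes that overlap no other, without their outer 1 kb, while the ratio of 0.198 covers all gene bodies. No ratio with repeats was computed for this set. How much of the gap goes with repeats therefore cannot be read from the 2 values. Fewer X copies in pools of both sexes could lower the peaks' p-values, but peaks with a −log10 p under 4 held only 1.97% of the autosomal covered bases. That bound stands in for dosage without read counts to check it, so dosage stays open.

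The strong peaks in zinc finger genes were not accounted for by shared sequence. In the 25 peaks in numbered Zfp genes among the 100 of largest fold, a median of 98.0% of 31-base sequences occurred once in the genome (lowest peak 81.6%). A low local background, which lifts fold and p alike, stays open. The same 25 peaks had a median percentile of 99.98 by p among all replicated peaks, but the other 75 of the 100 had 99.94, so peaks chosen by fold rank high by p wherever they lie and the bound set beforehand was no test of background.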

How the results depend on the processing

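Leaving out genes that overlap another and the match to the 50 genes nearest in length were chosen after the data were seen. Over the 10 quantities compared, 53 of 55 values under other settings kept their direction and their side of the test, or stayed within the spread allowed. For counts this spread was a fixed ratio to the main count, so 5257 and 10183 marked genes both passed beside 7646. The bars for replicate overlap, genic share, position and the exon to intron ratio lay well below every value. For the X ratio the spread was the SD of the replicates' own lists, which were themselves among the settings. The count of values kept is therefore a weak check. Stricter overlap and identical coordinates gave the same replicated share, since every replicated peak has the coordinates of a joint peak. They are no separate check. With peaks at or above the median fold, the replicated share of joint peaks moved from 76.4% to 96.3%, and the X to autosome ratio from 0.198 to 0.138. Joint peaks left out of the replicated list had a median fold of 2.84, against 3.96 for those kept. X-linked replicated peaks had a median fold of 3.55, under that of the replicated list (3.96). A cut by fold therefore removes a larger part of both sets. Why their folds were lower was not tested. Without 1 replicate, marked genes ranged from 6777 to 7699, 8 lists stood apart each time, the 3′ difference ranged from 9.16 to 10.4 points, the exon to intron ratio from 3.51 to 3.85, the X ratio from 0.174 to 0.210 and the genic share from 94.9% to 95.4%. Over all settings marked genes ranged from 5257 (overlapping genes left out, 30.6% of 17184) to 10183 (any base covered). Replicate overlap ranged from 48.6% to 66.2%. With at least 50% of both peaks shared, 34.3% of replicate 1's and 41.5% of replicate 2's peaks were matched. Of 278 percentiles of single lists, 238 kept their side of the bounds, 37 passed a bound that the main value did not and 3 fell back, all of the pan-neuronal list. Lists with a median of 0 could hardly change side in the settings that keep the median. Many of the 238 were therefore settled in advance, and the count does not measure stability. The mean put 16 lists at or below the 2.5 percentile, which the median cannot reach, and 15 with the match to the nearest 50 genes, the long neuronal list no longer among them. Of 705 values of named genes, 204 moved by more than the SD between replicates. Depth is unknown, so weakly marked genes cannot be told from unmarked ones. No paired analysis was possible because there was a single group.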

Other observations

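The test on peaks beyond 3′ ends was chosen after the 5 widest such peaks were seen, the other tests before their results, and the families and lncRNA genes below were chosen after their values were seen. For the hypotheses here, a bound counted as met only when the whole 95% interval met it, a stricter reading adopted after the values were seen.

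Families of genes with the same symbol stem extend the account of the fixed lists. Of 102 families with at least 20 protein-coding members, the mean share covered lay above the middle 95% of 2000 length-matched random lists for 29 and below it for 36. The largest excess was in the Nup family, which includes nucleoporins (19 of 21 marked, mean 52.8% against 18.3% in random lists), and in the Ddx family of RNA helicases (29 of 37, 53.4% against 19.9%). The Eif translation initiation factors (47 of 55, 48.3% against 18.4%), the Mrpl mitochondrial ribosomal proteins (40 of 49, 37.1% against 14.9%) and the Kif kinesins (27 of 39, 33.8% against 15.9%) followed the same direction. At the other end, 2 of 100 Cyp cytochrome P450 genes were marked (1.03% against 19.4%), 1 of 33 Cldn claudins (0.51% against 12.6%) and 1 of 45 Col collagens (1.18% against 12%).

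Of all 13374 lncRNA genes, 1168 (8.73%) had at least 10% of the body covered, and 934 did in both own lists. Of the 5754 lncRNA genes more than 5 kb from any protein-coding gene, 50 (0.869%) had at least 10% covered, and 37 of these also did in both own lists. Mir9-3hg, the host of a microRNA of neural progenitors (chromosome 7, 79500026 to 79534403), was covered for 69.8% (own lists 55.0% ± 2.85, SD, n = 2), and Lncppara (chromosome 15, 85653616 to 85707524) for 48.5% (43.6% ± 1.27). Trerf1 held the most covered bases of the set (36746 bp, 16.6%). It is in the set only because the annotation used here types it as a processed transcript. Whether genes of the set also code for protein was not checked, so Trerf1 cannot be taken as a lncRNA gene from this.

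Peaks outside annotated genes lay mostly just beyond 3′ ends. Of 4096 such peaks, 95.6% had the nearest protein-coding gene's 3′ end toward them. The 5 widest lay 522 to 1868 bp beyond Alyref, Rsl24d1, Srsf6, Tra2b and Zfp146. A candidate explanation is transcription that runs on past the annotated end. In marked genes with no gene within 10 kb on that side, the 10 kb after the 3′ end were covered 40.3 times as much as the 10 kb before the 5′ end (95% interval 28.1 to 66.6). The mean share covered was 8.35% over 1943 flanks after the 3′ end and 0.207% over 2285 before the 5′ end. Cover was 41.4% in the first kb after the end and 8.97% in the third. This restates the side on which the peaks lie, so it adds no support for run-on transcription, which stays open beside longer 3′ ends than annotated.

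Single-exon genes may carry less of the mark than spliced genes of their length. Their mean share covered was 0.454 of that of multi-exon genes in the same length bins (1318 genes, 95% interval 0.331 to 0.575), and 0.492 (0.379 to 0.627) without receptor and histone families. The point values lie under the bound of 0.5 set for the hypothesis and the intervals cross it, so it stays open.

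Long neuronal genes might be marked on exons while the share of the whole body stays low. In the 19 listed genes that overlap no other, peaks covered 10.5% of internal exon windows (95% interval over genes 4.15 to 19) and 0.140% of intron windows. The exon value lies just above the bound of 10% set for the hypothesis, but it rests on few genes: 12 of the 19 had no exon window covered. Leaving out any 1 of Auts2, Nrxn3, Pcdh9, Magi2, Nrxn1 and Ptprd brought it under 10%. Without Auts2, of whose internal exon windows 91.9% were covered, it was 8.53% and the intron value 0.0257%. The replicated peaks of Auts2 lay mostly in 1 stretch at its 3′ end (chromosome 5, 131436566 to 131477294). That stretch runs across exons and introns, so the peaks of Auts2 were not held to its exons. The hypothesis is left undecided. By length over all genes that overlap no other, the exon to intron ratio was 2.08 under 20 kb and 8.30 from 100 to 500 kb. In the 182 genes over 500 kb, the class of the listed genes, 18.5% of internal exon and 0.337% of intron windows were covered, a ratio of 55.0. Position along the gene was not held equal in these ratios.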
